A study of Homo sapiens with 12 samples.

How the data were processed

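MM.1S myeloma cells were sampled untreated (0 h) and at 6, 12, 24, 36 and 48 h in 0.5 nM bortezomib, with 1 poly(A) mRNA library and 1 ribosome footprint library at each time, per the labels. Each library was placed in its group by its title, and each column of the deposited table was matched to a library by its time and assay in the header. Whether the mRNA and the footprints of a time point came from 1 culture is not given in the sources used here.

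The deposited table holds raw read counts over coding sequences of UCSC transcripts, per the file headers. It also holds RPKM values for the same genes and libraries, which the authors scaled so that the median gene has nearly the same value, 44.6 in footprints and 17.79 to 17.8 in mRNA, as the values show. Bowtie 0.12.8 and the genome build hg19 are named in the submitters' processing notes. How reads matching several genes were counted, and the gene filter, are not given in the sources used here. The values show that the table is a filtered list of 4362 genes in which the lowest count of any gene in any library is 129. Its column totals are therefore those of the listed genes and not the depth of the libraries. Totals ran from 2849147 to 6376447 reads in mRNA and from 4428097 to 9836865 in footprints. The most abundant gene, ITGB7, took 2.42 to 3.72% of a library. The last row names no gene and holds the column medians, and it was left out of every step. 9 gene symbols had been turned into dates by a spreadsheet, and those genes are known by transcript ID only. 2 rows share 1 symbol and were kept apart. Gene names are those in the table. The gene annotation at hand is on another build than hg19, so no coordinates are given.

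Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Before the data were examined, the main tests were fixed as edgeR quasi-likelihood tests (robust, TMM scaling) of a linear slope on time in hours, scaled to 48 h, in the 6 mRNA libraries and in the 6 footprint libraries, each with 4 residual degrees of freedom. Translation efficiency was tested as the interaction of assay and time over the 12 libraries with the time point as a factor, with 4 residual degrees of freedom. Genes with Benjamini-Hochberg adjusted p under 0.05 were called. SE is the absolute slope divided by the square root of F. The planned filter of 10 reads in 3 libraries removed 0 genes, as did a filter of 50 reads, so neither tests anything.

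1 model was added after the data were examined. It takes time point as a factor and assay as a term over the 12 libraries (5 residual degrees of freedom), and gives each time against 0 h with the spread between assays as the error. All adjusted p-values of a change at a time point come from this model and edgeR's quasi-likelihood test. Log2 ratios to 0 h within 1 assay use TMM-scaled CPM with a prior count of 2. Their 95% intervals are exact binomial intervals of 1 library's reads against the other's, for counting error only.

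Of 27 gene lists fixed before the data were examined, the 21 with at least 5 measured members were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry asks whether its members moved at all. A list is said to pass or miss by camera unless another test is named. The rule for named genes was fixed then too. It takes up to 10 called genes per trend and direction, up to 4 members of each list that passes, and, at each time, the 5 highest and 5 lowest ratios among genes beyond a log2 ratio of 1 the same way in both assays with a mean CPM of at least 10. A panel of 35 genes could be named at any p, and 21 of them are in the table. Members named as examples of a list at a time point follow the same rule in the added model. Trend examples of a list are the members moving in its direction with the lowest p.

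The tests were tried on simulated counts for the same 4362 genes with 200 changed genes. Libraries were drawn independently with 1 common dispersion per test, other genes were flat, and changed genes in the trend tests followed straight lines. Curved courses in those tests, and differences between cultures shared by both assays, were not simulated. The rates below therefore do not carry over to data with either of these. The mRNA trend test recovered 78% of genes changed 2-fold per 48 h and 100% of those changed 3-fold, with 3 false calls. The footprint trend test recovered 66% at 2-fold with 3 false calls, and the translation efficiency test recovered 70% at 1.5-fold and 100% at 2-fold with 11 false calls. The model over both assays recovered 98% at 1.5-fold at 36 h with 12 false calls. Alternatives were other size factors, library totals, DESeq2 1.42.0, limma voom, the order of the time points and late against early time points. Others were a quadratic term, each time point or library left out, other prior counts, the authors' RPKM and genes with a mean of at least 500 reads. The authors' RPKM, the mean of 500 reads and the leaving out of single libraries were chosen after the data were examined. So was every alternative for the model over both assays.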

Results

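The data describe MM.1S cells, a human multiple myeloma line (a cancer of antibody-secreting plasma cells), exposed to 0.5 nM bortezomib, a drug that blocks the proteasome, the protease complex that degrades ubiquitin-tagged proteins. Cells were taken at 0 h, untreated, and at 6, 12, 24, 36 and 48 h of exposure. At each of the 6 time points 1 library of poly(A) mRNA and 1 library of ribosome footprints (mRNA fragments protected by translating ribosomes) were sequenced, 12 libraries in all. From 0 h to 48 h the reads in the table numbered 6376447, 4672856, 4334398, 3876239, 2849147 and 4813104 in mRNA and 4428097, 4806035, 5148425, 5568632, 9836865 and 4508418 in footprints. The table lists 4362 genes, each with at least 129 reads in every library. ATF4, DDIT3, HSPA1A and HMOX1 are among the genes not in the table and were not analysed here. No group has a replicate, and only the 0 h cells were untreated, so drug exposure and time in culture change together in every comparison. The series asks how transcript levels and ribosome occupancy move over 48 h of drug exposure.

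What changed at each time against 0 h was the first question. Proteasome subunit genes and stress-defence genes rose together to a peak at 24 to 36 h. Heat-shock chaperone genes were already up at 6 h. Cholesterol synthesis genes, glycolysis and hypoxia genes and ribosomal protein genes fell, each with its own timing. The largest rises at 36 h were in CLU, the secreted chaperone clusterin, at 9.88-fold (log2 change 3.30, SE 0.08), and in SQSTM1, the p62 receptor that carries ubiquitinated cargo to autophagy, at 9.05-fold (log2 change 3.18, SE 0.06, adjusted p = 1.91e-15). The deepest fall was in P4HA1, a prolyl hydroxylase of collagen synthesis that responds to hypoxia, which stood at 0.182 of its 0 h level at 6 h (log2 change -2.46, SE 0.11), at 0.157 at 12 h and at 0.202 at 48 h.

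These changes were tested in 1 edgeR quasi-likelihood model over all 12 libraries, with time point and assay as terms, so that a gene passes where its mRNA and its footprints moved alike. The test was chosen after the data were examined. Its errors measure how far the assays disagree. Both libraries of a time point may come from 1 culture, which the labels do not say, so p-values cover the spread between these libraries and may be technical, and the same 0 h libraries enter every comparison. Of 4362 genes, 847 were higher and 843 lower at 6 h, 993 and 927 at 12 h, 1004 and 1054 at 24 h, 1091 and 985 at 36 h, and 679 and 672 at 48 h. Most of these changes were small. A change beyond 2-fold was called for 6 genes up and 44 down at 6 h, 14 up and 67 down at 12 h, and 79 up and 62 down at 24 h. At 36 h there were 82 up and 63 down, and at 48 h 19 up and 18 down. Scaling by library totals alone called 1738 genes at 6 h, 60.2% of them higher against 50.1% with TMM scaling. It gave 63.5% against 51.7% at 12 h and 69.2% against 50.3% at 48 h, so the balance of small rises and falls rests on the scaling. Without the 6 h footprint library the 6 h count was 993, without the 12 h mRNA library the 12 h count was 1219, and without the 24 h footprint library the 24 h count was 1359. The 48 h count was 826 without the 48 h mRNA library and 812 without the 48 h footprint library.

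Proteasome genes rose as a complete set. All 32 subunits of the core and regulatory particles are in the table, and 17 of them rose at 6 h, 31 at 12 h, and 32 at each of 24, 36 and 48 h. The counts adjusted over the list alone were 19, 32, 32, 32 and 32. The median log2 change over the 32 genes was 0.20 at 6 h, 0.72 at 12 h, 1.19 at 24 h, 1.13 at 36 h and 0.65 at 48 h, and the 24 h set test gave a camera adjusted p of 3.35e-54. At 24 h PSMC4, an ATPase of the regulatory particle, had a log2 change of 1.72 (SE 0.07, adjusted p = 4.21e-11), PSMD2 of 1.49 (SE 0.06) and PSMB3 of 1.27 (SE 0.07). PSMB5, the subunit that bortezomib binds, reached a log2 change of 1.32 at 36 h (SE 0.09, adjusted p = 1.44e-08). NFE2L1, the transcription factor that drives proteasome genes, was at 0.03 at 12 h (SE 0.08), rose by 24 h to 0.36 (SE 0.08, adjusted p = 0.00193) and stood at 0.51 at 48 h. The proteasome call held with an estimated correlation at 12, 24, 36 and 48 h. In this model that correlation, 0.0371 at 24 h, comes from disagreement between the assays. It cannot see variation between cultures that both assays share, a limit for every list tested in this model. In the trend tests described below, the estimate for the proteasome list was 0.902 in mRNA and 0.946 in footprints. There the residuals also hold the shared departure of the members from a straight line, so those estimates do not measure variation between cultures. At 6 h the camera adjusted p was 6.73e-04, and adjusted p = 0.0728 with an estimated correlation.

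Chaperone genes were up from the first time point on. Of 14 measured heat-shock genes, 13 rose at 6 h, 14 at each of 12, 24 and 36 h, and 5 at 48 h, with 13, 14, 14, 14 and 7 adjusted over the list alone. HSPA8, the constitutive cytosolic HSP70, was 3.38-fold higher at 6 h in the model (log2 change 1.76, SE 0.07, adjusted p = 2.16e-10). Its CPM went from 1934.6 to 6449.1 in mRNA and from 2693.6 to 8877.8 in footprints. CPM is scaled within each assay and the model scales both assays together, so their fold changes differ slightly. Copies of HSPA8 exist elsewhere in the genome, and how reads shared with them were counted is not known. HSPH1 was 2.72-fold higher and DNAJA1 2.19-fold higher at 6 h. DNAJB1, an HSP40 co-chaperone, peaked at a log2 change of 1.77 at 24 h (SE 0.09), as did HSP90AA1, the inducible HSP90, at 1.76 (SE 0.07). By 48 h DNAJB1 was at 0.24 (SE 0.10, adjusted p = 0.0692) and HSP90AA1 at 0.31 (SE 0.07, adjusted p = 0.00211). The heat-shock set passed at all 5 times. Its call was lost at 36 h, where adjusted p = 0.0658 with an estimated correlation, and at 48 h, where adjusted p = 0.435 with an estimated correlation.

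Oxidative defence and ubiquitin-handling genes followed the proteasome genes. Of 8 measured NRF2 targets, 1 rose at 6 h, 7 at 12 h and 8 at each later time, the same numbers as adjusted over the list alone. Their median log2 change was 1.08 at 36 h, with TXNRD1, thioredoxin reductase, at 1.47 (SE 0.10), TALDO1 of the pentose phosphate pathway at 1.44 (SE 0.07) and PRDX1 at 0.85 (SE 0.06). FTL, the ferritin light chain, was 7.36-fold higher at 36 h (log2 change 2.88, SE 0.24, adjusted p = 7.74e-05). Processed pseudogenes of FTL exist, and how reads shared with them were counted is not given in the sources used here. Of 23 genes of the ubiquitin system, 15 rose and 2 fell at 36 h (15 and 3 adjusted over the list alone). UCHL1, a deubiquitinase, was 6.40-fold higher (log2 change 2.68, SE 0.07), and UFD1L and NPLOC4, the partners that take ubiquitinated proteins to the p97 unfoldase, were at 1.44 (SE 0.10) and 1.25 (SE 0.09). The ubiquitin set passed at 36 h with camera (adjusted p = 4.97e-08), with adjusted p = 0.0658 with an estimated correlation. ABCB6, a porphyrin transporter, was 4.74-fold higher at 36 h. The autophagy list was led by SQSTM1 and CTSD, the lysosomal protease cathepsin D. Earlier its members went both ways. At 6 h 4 fell and 0 rose, at 24 h 4 fell and 2 rose (median log2 change -0.11), and at 36 h 3 rose and 2 fell. The counts adjusted over the list alone were the same. At 48 h 3 of its 10 members rose and none fell (4 adjusted over the list alone), with CTSD 3.49-fold higher and LAMP2 at a log2 change of 0.31 (SE 0.08). The list's camera adjusted p was 5.14e-07 at 48 h, and adjusted p = 0.0598 with an estimated correlation.

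**Figure D1:**
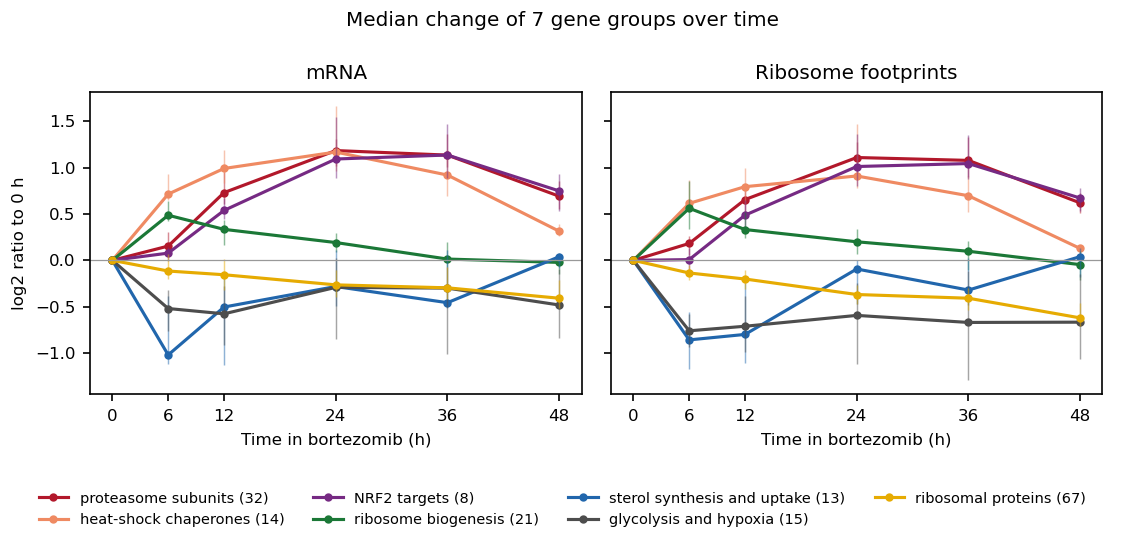
Median log2 ratio to 0 h (vertical axis) against time in bortezomib in hours (horizontal axis) for 7 gene groups, in mRNA on the left and in ribosome footprints on the right. Points are medians over the measured members, whose number is in the key, thin vertical lines are the quartiles of the members, and each time point is 1 library per assay. The proteasome median in mRNA reaches 1.18 at 24 h, and the sterol median is lowest at 6 h, at -1.02.

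Cholesterol synthesis and uptake genes were lowest at 6 h and near their 0 h level at 48 h. Of 13 measured, 10 fell and 1 rose at 6 h, 8 fell at 12 h, 6 fell and 2 rose at 24 h, 7 fell and 2 rose at 36 h, and at 48 h 2 fell and 2 rose (10, 9, 6, 7 and 2 falls adjusted over the list alone). The median log2 change was -0.95, -0.64, -0.16, -0.29 and 0.01, so the return was not steady. INSIG1, a sterol-sensing regulator, was at 0.274 of its 0 h level at 6 h (log2 change -1.87, SE 0.08) and at -0.003 on the log2 scale by 48 h (SE 0.07, adjusted p = 0.98). HMGCS1, a cholesterol synthesis enzyme, fell by 1.32 at 6 h (SE 0.09, adjusted p = 3.19e-08). The set's camera adjusted p was 4.84e-16 at 6 h and held with an estimated correlation (adjusted p = 0.00318 with an estimated correlation).

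Glycolysis and hypoxia genes fell by 6 h and stayed low. Of 15 measured, 12 fell and 1 rose at 6 h, and 9 fell and 1 rose at 48 h (12 and 9 falls adjusted over the list alone). The median log2 change was -0.64 at 6 h, -0.63 at 12 h, -0.52 at 24 h, -0.52 at 36 h and -0.51 at 48 h. LDHA, lactate dehydrogenase A, had a log2 change of -0.91 at 6 h (SE 0.06, adjusted p = 1.64e-08), PKM2, pyruvate kinase, of -0.81 (SE 0.06) and NDRG1, a hypoxia-induced gene, of -1.51 (SE 0.10). SLC16A3, a lactate exporter outside that list, stood at 0.291 of its 0 h level at 6 h. The set's camera adjusted p was 1.73e-16 at 6 h. Its call was lost at 24 h, where adjusted p = 0.156 with an estimated correlation, and at 36 h, where adjusted p = 0.0746 with an estimated correlation. Other genes with deep falls were CCL3, a chemokine, at 0.23 of its 0 h level at 6 h, RHOB, a small GTPase, at 0.22 at 12 h, RAB11FIP1, a Rab11 effector, at 0.183 at 24 h, LGALS1, galectin-1, at 0.282 at 24 h, and MARCKS, an actin-binding kinase substrate, at 0.24 at 36 h.

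Genes of the protein synthesis machinery split. All 21 measured ribosome biogenesis factors rose at 6 h, 16 at 12 h, 9 at 24 h and 7 at 36 h, where 1 fell, and at 48 h none rose and 3 fell. The counts adjusted over the list alone were the same. At 6 h UTP20 had a log2 change of 1.04 (SE 0.08), POLR1B of 0.86 (SE 0.08) and NOP56 of 0.71 (SE 0.07). The set passed at 6 h (camera adjusted p = 6.92e-16; adjusted p = 0.00318 with an estimated correlation) and at 12 h, and missed the threshold at the later times. MYC, a driver of ribosome biogenesis counted among these 21 genes, rose by 6 h to 0.53 (SE 0.07, adjusted p = 2.49e-05) and was at -0.28 at 48 h (SE 0.07, adjusted p = 0.00584). Ribosomal protein genes fell in growing numbers, with the reservation that they have many near-identical copies and the counting of shared reads is not known. Of 67 measured, 13 fell and 1 rose at 6 h, 29 fell at 12 h, 45 at 24 h, 46 at 36 h and 58 at 48 h (12, 30, 51, 48 and 62 falls adjusted over the list alone). At 48 h RPS4X fell by 0.87 (SE 0.07, adjusted p = 2.79e-07) and RPL3 by 0.68 (SE 0.06). The 48 h camera adjusted p was 1.86e-26, and adjusted p = 0.0684 with an estimated correlation. EEF2, the translocation elongation factor, fell by 0.46 at 48 h (SE 0.09). Of 16 translation factors with 5 prime TOP mRNAs, 11 fell at 48 h (12 adjusted over the list alone), with adjusted p = 0.332 with an estimated correlation.

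Endoplasmic reticulum genes moved both ways, DNA replication genes rose early and plasma cell genes fell. Of 22 unfolded protein response genes of the endoplasmic reticulum, 4 rose and 5 fell at 6 h and 9 rose and 5 fell at 24 h (5 and 6, and 9 and 5, adjusted over the list alone). The set did not pass camera at any time, with its lowest camera adjusted p, 0.192, at 6 h. By fry it was lower at 6 h (adjusted p = 0.000144) and 36 h (0.0172) and higher at 24 h (0.00309) and 48 h (0.0126). Members went both ways. HERPUD1, a factor of endoplasmic reticulum-associated degradation, fell by 1.09 at 6 h (SE 0.07), and HSPA5, the chaperone BiP, rose by 24 h to 0.54 (SE 0.06, adjusted p = 1.42e-06). XBP1, whose assays went apart, did not pass at any time. At 36 h its mRNA gave a log2 ratio of 0.18 (95% exact interval for counting error 0.10 to 0.26) and its footprints -0.79 (-0.87 to -0.71), and its ratio slope did not pass either (adjusted p = 0.507). Of 16 DNA replication genes, 10 rose at 6 h and 14 at 12 h (12 and 15 adjusted over the list alone), with MCM6 at 0.56 (SE 0.07) and MCM5 at 0.54 (SE 0.08) at 6 h. Their call was lost with an estimated correlation (adjusted p = 0.112 with an estimated correlation at 6 h). Of 18 mitotic genes, 7 rose at 24 h (4 adjusted over the list alone; camera adjusted p = 0.287). Of 25 other initiation factors, 14 rose and 1 fell at 6 h (14 and 1 adjusted over the list alone; camera adjusted p = 0.00644, and adjusted p = 0.203 with an estimated correlation). Of 17 plasma cell genes, 10 fell and 2 rose at 36 h (11 and 2 adjusted over the list alone). TNFRSF17, the receptor BCMA, fell by 0.65 (SE 0.07) and CCND2, cyclin D2, by 0.65 (SE 0.08). The set's adjusted p at 36 h was 0.0119, and adjusted p = 0.0988 with an estimated correlation. IRF4, on which myeloma cells depend, rose by 24 h to 0.51 (SE 0.06, adjusted p = 4e-06). Of 10 ATF4 targets, 4 rose at 48 h (4 adjusted over the list alone), PSAT1 of serine synthesis at 0.71 (SE 0.12) among them. Their camera adjusted p was 0.043, and adjusted p = 0.332 with an estimated correlation. Of 18 tRNA synthetases, 13 rose and 2 fell at 36 h (13 and 2 adjusted over the list alone; camera adjusted p = 0.0321, and adjusted p = 0.117 with an estimated correlation), HARS at 0.76 (SE 0.08) and MARS at 0.58 (SE 0.07) among them.

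Among the genes in the table, apoptosis, NF-kB and respiratory chain groups showed little movement relative to the other genes. The table holds 7 of 16 p53 targets, 5 of 15 BCL2-family genes and 6 of 16 NF-kB targets. CDKN1A, PMAIP1 and BCL2L11 are not in it. Since every listed gene has at least 129 reads in every library, genes induced from a low level may be missing. The p53 and BCL2-family sets did not pass camera at any time. By fry the p53 set was lower at 6 h (adjusted p = 0.0177), 12 h (0.00172) and 24 h (0.00597), and the BCL2-family set did not pass. MCL1, a survival factor, was at -0.27 at 24 h (SE 0.08, adjusted p = 0.00924) and at -0.20 at 48 h (SE 0.08, adjusted p = 0.0588). Of 6 NF-kB targets, 4 fell at 12 h (4 adjusted over the list alone). The 12 h camera adjusted p was 0.0296, and adjusted p = 0.139 with an estimated correlation, and the 12 h median was -0.32 in mRNA and -0.04 in footprints. With library totals only, that footprint median was 0.02. Of 40 nuclear-encoded respiratory chain genes, 13 rose and 3 fell at 36 h (13 and 3 adjusted over the list alone; camera adjusted p = 0.17), with NDUFB9, a complex I subunit, at 0.72 (SE 0.09). By fry this set was higher at 24 h (adjusted p = 0.0134) and 36 h (0.00226). No gene of the interferon, myeloid or epithelial and stromal lists was in the table. CD28, the only T cell list member in it, was at -0.31 at 24 h (adjusted p = 0.00521). The lists of 3 mRNAs that resist eIF2alpha phosphorylation and of 4 replicative histone genes were too short for a set test, and of these PPP1R15B fell by 0.53 at 24 h (adjusted p = 0.000914).

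**Figure D2:**
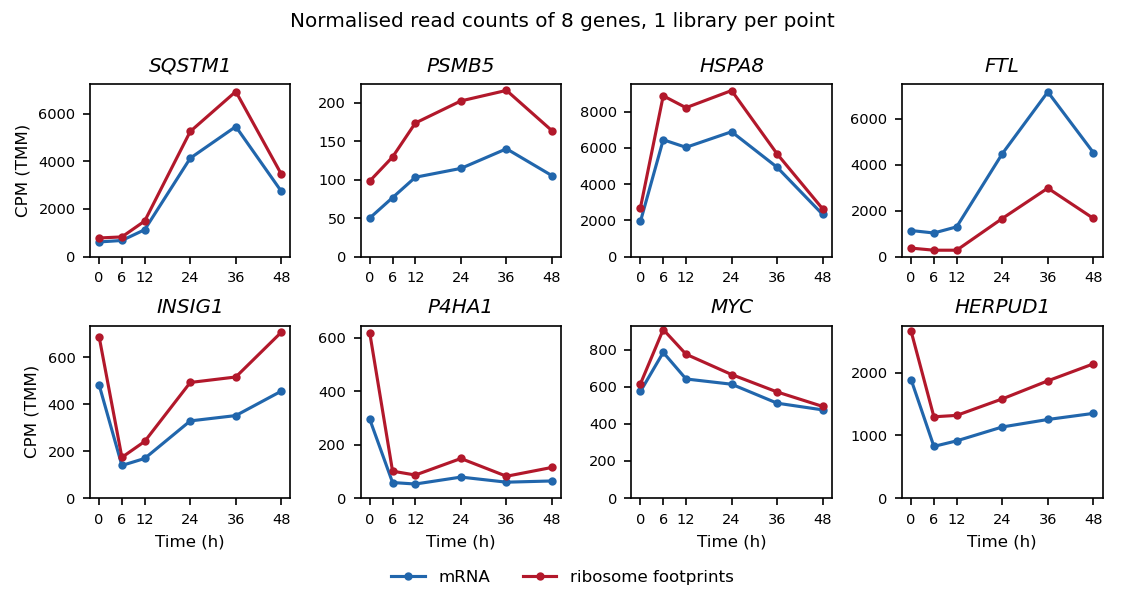
Normalised read count (CPM with TMM scaling, vertical axes starting at 0) against time in hours for 8 genes, with mRNA in blue and ribosome footprints in red. Each point is 1 library, so no error is drawn. SQSTM1 in mRNA goes from 611.7 CPM at 0 h to 5458.2 CPM at 36 h, and P4HA1 in mRNA from 294.9 CPM at 0 h to 58.0 CPM at 6 h.

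Taken singly, the ratios of the libraries were far beyond counting error for these genes. The 95% exact intervals cover counting error only, since the reads carry no molecular identifiers. SQSTM1 mRNA at 36 h rested on 15560 reads against 3744 at 0 h, a log2 ratio of 3.16 (95% interval 3.11 to 3.21), and its footprints gave 3.16 (3.11 to 3.21). For P4HA1 at 6 h, 273 mRNA reads against 1805 gave -2.35 (-2.54 to -2.16), and the footprints gave -2.62 (-2.76 to -2.48). Genes beyond 2-fold in both assays, a count with no test, numbered 3 up and 37 down at 6 h, 4 and 51 at 12 h, 64 and 42 at 24 h, 54 and 48 at 36 h, and 14 and 17 at 48 h. With library totals only they were 5 up and 29 down at 6 h, 11 and 38 at 12 h and 20 and 12 at 48 h. Against 10000 random lists matched on expression, the proteasome mRNA median lay at the 100 percentile from 12 h on and the sterol median at the 0 percentile at 6 h.

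The next question was which genes rose or fell steadily over the 48 h, the test fixed before the data were examined. No gene passed this test, and no list passed it with an estimated correlation. Proteasome genes had a median mRNA slope of 0.84 (log2 change per 48 h) and a median footprint slope of 0.78, NRF2 targets 0.85 and 0.86, and ribosomal protein genes -0.37 and -0.55. SQSTM1 had slopes of 3.30 in mRNA (SE 0.86, adjusted p = 0.311) and 3.30 in footprints (SE 0.83, adjusted p = 0.178), and CTSD of 2.25 (SE 0.35, adjusted p = 0.186) and 2.52 (SE 0.41, adjusted p = 0.109). RPS4X had -0.68 (SE 0.12) and -0.92 (SE 0.14). In mRNA, UCHL1 had a slope of 2.61, PHGDH of serine synthesis of 0.78 and GNL3, a nucleolar factor, of -0.41. edgeR called 0 genes in mRNA and 0 in footprints, with 552 and 618 genes at an unadjusted p under 0.05. limma voom called 0 and 0, DESeq2 53 and 287. Adjusted over the list alone, 30 ribosomal protein genes fell in mRNA and 61 in footprints, 4 and 8 of the 8 NRF2 targets rose, and 0 and 0 proteasome genes passed.

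By camera 9 of 21 lists passed in mRNA, 7 up and 2 down, and 10 in footprints, 6 up and 4 down. None of these calls held with an estimated correlation. A rise and return shared by the members counts as scatter around the line and can raise that estimate. The proteasome list had adjusted p = 0.567 with an estimated correlation in mRNA and 0.612 in footprints, and the ribosomal protein list 0.422 and 0.312. The others that passed in both assays were the ATF4 (0.567 and 0.484 with an estimated correlation), NRF2 (0.567 and 0.484), autophagy (0.567 and 0.418), ubiquitin (0.768 and 0.827) and ribosome biogenesis lists (0.768 and 0.827), the last of these down. In mRNA alone the tRNA synthetase (0.567) and respiratory chain lists (0.606) passed. In footprints alone the TOP translation factor (0.462, down), sterol (0.827, up) and glycolysis and hypoxia lists (0.827, down) passed. A test passed in 1 assay and missed in the other does not show a difference between them.

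A straight line does not describe genes that rise and then return, such as the heat-shock genes. A fit with a quadratic term was fixed beforehand as an alternative. It tests slope and quadratic term together, so a gene with a straight course can pass as well as a curved one. By this test 656 genes (15% of the table) passed in mRNA and 370 (8.48%) in footprints. Of these, 274 passed in both, where independent lists would share 56. A joint test of all time points in the model over both assays called 2820 genes (64.6% of the table). Among them the largest change, whether or not called singly, fell at 6 h for 650, at 12 h for 437, at 24 h for 656, at 36 h for 796 and at 48 h for 281. Without the 48 h libraries the straight line called 135 genes in mRNA, 92 of them up, and 232 in footprints, 174 of them up.

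Translation efficiency, the ratio of footprints to mRNA, showed whether a gene's ribosome occupancy moved apart from its transcript relative to the other genes. Since counts were scaled between libraries, a change of translation shared by all genes would not be seen. In the planned test of assay by time over all 12 libraries, SPTAN1 (uc004bvm.4), which encodes a spectrin of the membrane skeleton, gained 1.20 on the log2 scale per 48 h (SE 0.18, adjusted p = 0.00785). PABPC1 (uc003yjs.1), the cytoplasmic poly(A)-binding protein, fell by 1.02 (SE 0.16, adjusted p = 0.00785), HNRNPA1 (uc001sfl.3), a splicing factor, by 0.78 (SE 0.15, adjusted p = 0.0471) and YBX1 (uc001chs.3), an mRNA-binding protein, by 0.71 (SE 0.13, adjusted p = 0.027). PABPC1 and HNRNPA1 are on the list of mRNAs with a 5 prime TOP motif. These were the only 4 of 4362 genes called, with 590 at an unadjusted p under 0.05. The call count was 0 without the 6 h libraries, 1 without the 12 h or the 36 h libraries, 76 without the 48 h libraries and 0 in a model with no time-point factor.

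The 4 genes had different courses. The PABPC1 ratio was at -0.50 at 6 h, -0.87 at 24 h and -1.11 at 48 h relative to 0 h, with its mRNA at 0.16 at 48 h and its footprints at -0.95. SPTAN1 had a single step. Its ratio was 0.17 at 24 h, 1.10 at 36 h and 1.02 at 48 h, from 223 footprint reads at 0 h, 314 at 24 h, 1113 at 36 h and 487 at 48 h, while its mRNA ratio to 0 h was 0.03 at 36 h (95% exact interval for counting error -0.05 to 0.10). These reads are not scaled, and the 36 h footprint library has the highest total. Scaled footprint log2 ratios to 0 h were 1.13 at 36 h and 0.99 at 48 h. PABPC1, HNRNPA1 and YBX1 have processed pseudogenes that reads of these genes can match.

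**Figure D3:**
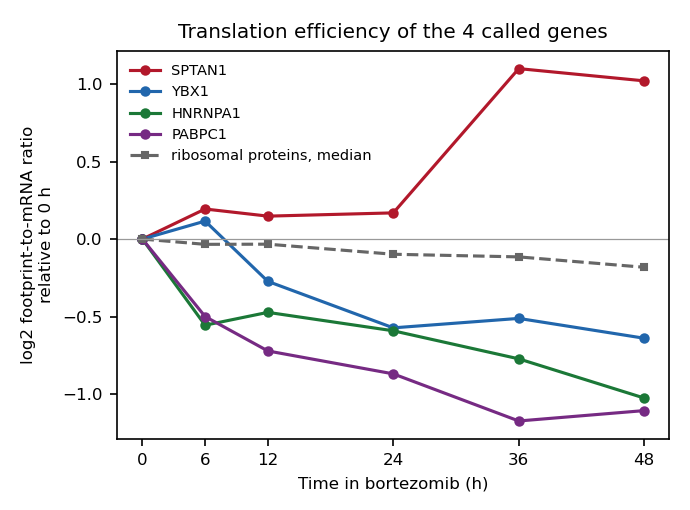
Change of the log2 footprint-to-mRNA ratio relative to 0 h (vertical axis) against time in bortezomib in hours (horizontal axis) for the 4 called genes and, dashed, the median of 67 ribosomal protein genes. Each point rests on 1 mRNA and 1 footprint library. SPTAN1 steps from 0.17 at 24 h to 1.10 at 36 h, and PABPC1 reaches -1.11 at 48 h.

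Ribosomal protein and other TOP mRNAs lost ratio as groups in the camera test. The median slope was -0.17 for 67 ribosomal protein genes (camera adjusted p = 1.39e-11) and -0.23 for 16 translation factors (camera adjusted p = 1.5e-08), each with adjusted p = 0.121 with an estimated correlation. Adjusted over the list alone, 10 and 7 members fell, led by RPL22 and PABPC1. Heat-shock genes (median -0.14, camera adjusted p = 0.00556, and adjusted p = 0.637 with an estimated correlation) and mitotic genes (median -0.06, camera adjusted p = 0.00687, and adjusted p = 0.806 with an estimated correlation) also passed with camera, with 4 and 3 members falling adjusted over the list alone. Proteasome genes (median slope -0.03, adjusted p = 0.679) and NRF2 targets (0.01, adjusted p = 0.829) did not pass.

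How closely footprints followed mRNA was measured across genes, which are not independent replicates. Pearson's r between the log2 ratios to 0 h of the 2 assays was 0.786 at 6 h, 0.78 at 12 h, 0.845 at 24 h, 0.766 at 36 h and 0.693 at 48 h, and Spearman's rho was 0.74, 0.724, 0.787, 0.679 and 0.594. The fitted slopes correlated at 0.804. The difference between assays had an SD of 0.23 to 0.31 on the log2 scale, and the changes themselves an SD of 0.33 to 0.45 in mRNA. No gene moved beyond 2-fold in opposite directions in the 2 assays at any time. Genes beyond 2-fold in at least 1 assay numbered 83 at 6 h, 203 at 24 h and 232 at 36 h. SQSTM1 had the same log2 ratio of 3.16 in both assays at 36 h, and UCHL1 had 2.64 in mRNA and 2.66 in footprints.

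**Figure D4:**
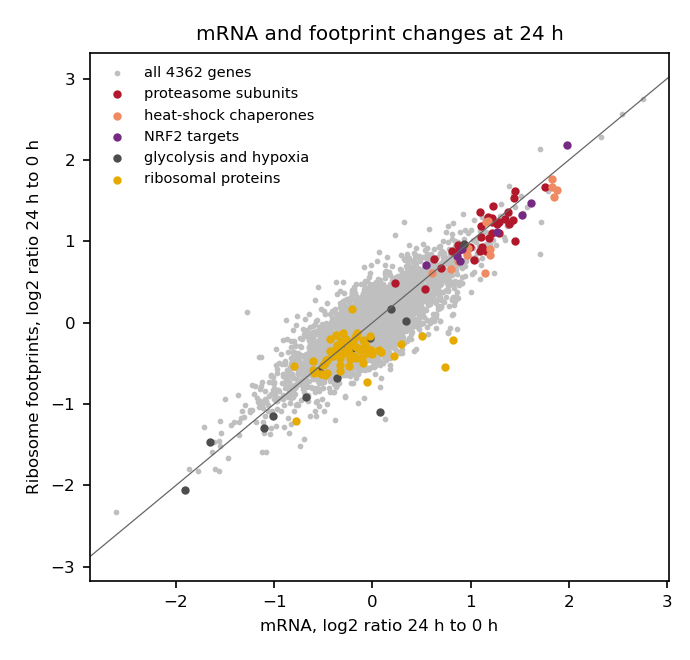
Log2 ratio of 24 h to 0 h in ribosome footprints (vertical axis) against that in mRNA (horizontal axis), with 1 point per gene, 5 gene groups in colour and the line of equal change. Pearson's r across the 4362 genes is 0.845, and the proteasome genes lie at the upper right.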

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

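The tests of the state of the 0 h culture, of the 36 h libraries and of the strongest list in each order were chosen after their results were seen. The test of each time point in both assays and the immediate early list were also chosen after the data were examined.

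4 genes stood out because their footprints and their mRNA took different slopes over time, by the interaction test of edgeR. The ratio of SPTAN1 had a slope of 1.20 per 48 h (adjusted p = 0.00785), PABPC1 of -1.02 (adjusted p = 0.00785), HNRNPA1 of -0.78 (adjusted p = 0.0471) and YBX1 of -0.71 (adjusted p = 0.027). As a count these 4 calls cannot be set apart from chance: 8 of 100 orders of the time points, the real one among them, gave as many, and the highest other order gave 260. An order that calls many times the real count points to a structure of the samples, which no test here identifies.

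The falling footprint-to-mRNA ratio of ribosomal protein and translation factor mRNAs is a pattern of 83 genes, 68 of them with a negative slope, with a median of -0.19 per 48 h. Coding length, taken from the ratio of reads to RPKM, and mRNA abundance do not account for it: the median was -0.17 with a smooth trend on length removed and -0.24 with one on abundance removed. Nor does 1 time point, since the weakest median, that without 48 h, was -0.14. Chance is not excluded: these lists were picked among 21 by this slope, and in 36 of all 720 orders of the time points (a share of 0.05) the strongest list was as strong as in the real order (7.99, highest other 9.52), and both calls had adjusted p = 0.121 with an estimated correlation. What also stays open is GC content, not tested because no genome was at hand, reads shared with pseudogenes, and a regulated loss of ribosomes from TOP mRNAs under the drug, which was not tested.

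Hypoxia and glycolysis genes and immediate early genes were low at every later time. Over the 32 genes of both lists the median log2 ratio at 6, 12, 24, 36 and 48 h was -0.67, -0.73, -0.49, -0.36 and -0.57 in mRNA and -0.78, -0.88, -0.77, -0.71 and -0.71 in footprints. With library totals only, the 6 h median was -0.60 in mRNA and -0.70 in footprints. That scaling raised the 6 h median of all genes by only 0.07 in mRNA and 0.079 in footprints. It could not have removed the fall, so this test does not decide whether scaling contributes. With library totals the 6 h median of all genes was 0.054 in mRNA and 0.056 in footprints, so the lists were low relative to the other genes. Each scaling is relative, and a change of RNA content shared by all genes would not be seen. The 6 h change was 1.06 times the mean of the changes at 24, 36 and 48 h in footprints and 1.41 times in mRNA, where for proteasome genes these shares were 0.195 and 0.153. A state of the 0 h culture, such as crowding or handling before the drug, and a fast effect of the drug cannot be told apart, because 0 untreated libraries were taken after 0 h.

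Smaller changes at 48 h than at 36 h could come from untreated-like cells or RNA in the 48 h samples. Mixing alone, with the treated cells otherwise as at 36 h, would take every gene back by the same share. The median share of return was 0.717 for heat-shock genes against 0.458 for NRF2 targets in mRNA. In footprints it was 0.886 against 0.516, so the difference was at least 0.259. These lists already moved apart from 24 to 36 h in mRNA, heat-shock genes from 1.17 to 0.92 and NRF2 targets from 1.09 to 1.14. Unequal shares therefore argue against mixing alone only. Ribosomal protein genes moved further from 0 h instead, with shares of -0.15 and -0.288. The 36 h libraries alone do not account for the peak, since the medians of the proteasome, heat-shock and NRF2 lists at 24 h lay above those at 48 h by at least 0.34 in both assays. Mixing joined with further change of the treated cells, loss of active drug and adaptation of the cells stay open and were not tested.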

How the results depend on the processing

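The model over both assays, genes with a mean of at least 500 reads, the authors' RPKM and the leaving out of single libraries in that model were chosen after the data were examined. No paired analysis between time points was possible because each group holds 1 library, and the translation efficiency test pairs the assays of a time point by its time-point factor. The filters of 10 and 50 reads removed no gene and say nothing. Where counts moved by more than 1.5 times, the cause was not tested unless fewer genes were tested. The mRNA trend count of 0 became 1 with genes of at least 500 reads on average, 53 with DESeq2, 3 with the order of the time points, 4 with late against early times and 656 with a quadratic term, and 0 to 135 with 1 time point left out. The footprint count of 0 became 287 with DESeq2, 33 with late against early and 370 with a quadratic term, and 0 to 232 with 1 time point left out. The translation efficiency count of 4 became 13 with DESeq2 size factors, 12 with genes of at least 500 reads, 18 with DESeq2, 47 with the order of the time points, 0 with late against early and 0 with no time-point factor, and 0 to 76 with 1 time point left out. No slope of the 4 genes changed sign in any of these fits. Of 16 alternatives each, SPTAN1 lost its call in 4, PABPC1 in 4, YBX1 in 5 and HNRNPA1 in 10. The 16 include the filter settings that removed no gene and could not lose a call. In the model over both assays, 1105 genes were called at 6 h among genes of at least 500 reads (fewer genes tested). Without 1 library the counts ran from 993 to 1756 at 6 h, 1219 to 1992 at 12 h, 1359 to 2112 at 24 h, 1566 to 2047 at 36 h and 812 to 1431 at 48 h. The 787 alternative values of the 47 named changes at a time point all kept their sign and their side of the threshold. These changes were picked from the same libraries as the largest beyond a log2 ratio of 1 in both assays. Such stability was therefore likely from the start and says little about other genes. Lists passing in the trends went from 9, 10 and 4 to 0, 0 and 0 with an estimated correlation and to 1, 1 and 0 with fry, and with 1 time point left out ran from 7 to 13, 6 to 11 and 3 to 5. In the model over both assays, lists went from 8, 12, 9, 9 and 10 to 4, 7, 4, 2 and 3 with an estimated correlation, and fry gave 15 at 6 h, 19 at 24 h and 16 at 36 h. Library totals moved the median of all genes by 0.035 to 0.101 on the log2 scale. Rises beyond 2-fold in both assays went from 3 to 5 at 6 h and from 4 to 11 at 12 h with library totals, and totals over both directions moved by less than 1.5 times.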

Other observations

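The lysosome and immediate early lists and the pair CIRBP and RBM3 were chosen after the data were examined, and the set tests of these lists are adjusted here together with the 21 lists fixed beforehand. Lysosomal genes rose late. Of 47 measured, 15 fell and 0 rose at 6 h, and by 48 h 20 rose and 4 fell (22 and 5 adjusted over the list alone), with a median log2 change of 0.19 (camera adjusted p = 2.9e-05, and adjusted p = 0.104 with an estimated correlation). CTSD was at 1.80 (SE 0.08) and PSAP, the precursor of the saposins, at 1.07 (SE 0.06), each by edgeR at 48 h.

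Immediate early and growth factor response genes fell at 6 h and stayed low. Of 17 measured, 12 fell and 1 rose at 6 h and 16 fell at 12 h (12 and 16 adjusted over the list alone), and the list held with an estimated correlation at 6, 12, 24 and 48 h, but not at 36 h, where adjusted p = 0.0575 with an estimated correlation. JUND fell by 1.78 at 6 h (SE 0.11), KLF2 by 1.55 (SE 0.13), ZFP36 by 1.45 (SE 0.13) and DUSP4, a MAP kinase phosphatase, by 1.31 (SE 0.09), and MYC was the gene that rose. The cold-inducible RNA-binding protein genes CIRBP and RBM3 fell more slowly. CIRBP fell by 0.50 at 6 h, 1.11 at 24 h and 1.33 at 36 h (SE 0.12), and was at -0.946 at 48 h (SE 0.115). RBM3 was at 0.21 at 6 h (adjusted p = 0.116) and at -0.90 at 48 h (SE 0.11).

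The mRNA and footprint libraries of a time point deviated together. Correlations of their deviations from the mean over time, across genes, were 0.783 at 0 h, 0.822 at 6 h, 0.723 at 12 h, 0.857 at 24 h, 0.714 at 36 h and 0.718 at 48 h, where the highest correlation with a footprint library of another time was 0.104, 0.479, 0.457, 0.545, 0.706 and 0.308. Of 100 pairings of the mRNA with the footprint libraries, 1, the real one, gave as many as the 2820 genes called by the joint test of all time points in both assays, and the highest other gave 566. This shows that the libraries of a time point resemble each other, and a chance difference between single cultures that both assays share would do the same, so it leaves chance between cultures open. For slope and quadratic term tested together, 1 of 100 orders of the time points, the real one, gave as many genes as the 656 in mRNA. The highest other order gave 462. In footprints 2 of 100 orders, the real one among them, gave as many as the 370, and the highest other gave 394. So few orders of these libraries gave as many calls. Differences between single cultures can also follow the order of time, which reordering cannot tell apart, so chance between cultures stays open here too.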
